A study of Homo sapiens with 9 samples.

How the data were processed

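RNA sequencing libraries of the human BPDCN cell line CAL-1 were analysed, 9 in all: 3 controls (NTC) and 3 for each of 2 CRISPR interference groups against KHSRP. Per the labels' protocols, total RNA was extracted with a column kit (NucleoSpin RNA Plus XS) and libraries carry the name Roche Kapa. The authors deposited 1 table of TPM per gene symbol; TPM divides read counts by transcript length and scales each library to a sum of 1000000, and each deposited column has that sum. The build was hg38, per the submitters' processing notes; the aligner's version, the counting tool, the annotation and the use of strand are not given in the sources used here. The table has older symbols for some genes, which were matched to the gene lists through synonyms in the reference table. Groups and replicate numbers were taken from the sample titles, and each column was matched to its sample by the label that gives its name. The labels give 1 shared batch for all libraries. Nothing in them says that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. No 2 libraries held identical values.

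TPM holds no read totals, so no count model was used and the depth in reads is unknown. Relative depth was estimated from the spacing of low TPM values of the same gene in pairs of libraries, and ran from 0.98 to 1.83 times NTC replicate 1. The precision of low genes cannot be stated from counts and rests on the replicates.

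Genes with a mean TPM of at least 1 over the 9 libraries (10939) were tested on log2(TPM + 1), a pseudocount of 1, with limma 3.58.1 in R 4.3.3 (eBayes with an intensity trend, two-sided tests). One fit held all 3 groups without covariates, because groups of 3 need a shared estimate of the spread. Contrasts were each guide minus control, the mean of the guides minus control, and guide 2 minus guide 1. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, and genes under 0.05 were called. Gene lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry; 44 lists were fixed before the data were examined, and 40 had at least 5 tested members. Symbols of the list of mitochondrially encoded genes matched no row. Single genes were also compared by exact permutation tests of TPM over the 84 divisions of 9 libraries into 6 and 3. Gene positions are from GENCODE 29 on the same build. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the depth estimate, the reference and the figures.

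The genes named follow a rule set before the data were examined: 6 genes of interest (KHSRP, SLC23A1, SLC23A2, FUBP1, FUBP3 and TET2); up to 12 genes per direction with the largest fold changes among those called by both guides in the same direction with all 6 knockdown libraries beyond all 3 controls; up to 4 members of each described list with the smallest adjusted p, or its most abundant member; 4 genes per direction that differ between the guides; 4 per direction called by each guide; and called neighbours of KHSRP. All 9 genes called on average over the guides are also named. After seeing that the replicate 3 libraries stood apart, the rule was also applied to a fit with a term for those libraries.

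The method was tested on simulated libraries with 68 genes changed 1.25-fold, 66 changed 1.5-fold and 66 changed 2-fold. For the mean of the guides against control, over 10939 genes, 47.1%, 80.3% and 98.5% of these were called, with 6 false calls. With the replicate 3 term and its smaller residual spread the shares were 57.4%, 90.9% and 100%. These shares depend on the spread of each gene and on how many genes change, and may be lower where fewer change. In the real data GZMB, with a log2 fold change of 0.99, was not called without the term.

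Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no filter, a filter at a mean TPM of 5, median-ratio rescaling, quantile normalization, a replicate block, robust eBayes, array weights, fits of only the groups compared, a minimum log2 fold change of 1, and leaving out each library. The term for replicate 3, leaving out each library in the fit with that term, a fit of replicates 1 and 2 alone, and tests of the gene lists for a difference between the guides were added after seeing the data. GC content, transcript length and 3' UTR motifs were taken from GENCODE 29 transcripts, matched for 10574 of the tested genes (96.7%).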

Results

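The study measured gene expression by RNA sequencing in CAL-1, a human cell line of blastic plasmacytoid dendritic cell neoplasm (BPDCN), a leukemia of the plasmacytoid dendritic cell lineage. KHSRP, a KH-domain RNA-binding protein known for promoting the decay of mRNAs with AU-rich elements, had been knocked down by CRISPR interference. The 9 libraries fall into 3 groups of 3: a control group labelled NTC, and knockdown groups labelled KHSRPi#1 and KHSRPi#2. The labels do not say what the numbers stand for; they are taken here to be 2 guide RNAs and called guide 1 and guide 2. The series title names SLC23A1, a vitamin C transporter, beside KHSRP, so that gene is reported whatever its result. Values were TPM, a length-scaled share of each library's transcripts, for 25540 gene symbols, with between 13966 and 14462 symbols above 0 in each library. TPM keeps no read totals; the spacing of low values puts the depth of the libraries between 0.98 and 1.83 times that of NTC replicate 1. Of the symbols, 10939 had a mean TPM of at least 1 and were tested. Fold changes are on the log2(TPM + 1) scale, which understates the change of genes with low TPM.

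KHSRP mRNA was strongly reduced in every knockdown library. It was at 237 ± 19.1 TPM in the controls, 35.1 ± 0.0134 TPM with guide 1 and 35.3 ± 1.49 TPM with guide 2 (mean ± SD, n = 3 each). These levels are 14.8% and 14.9% of the control mean, and the 6 libraries lay between 14.2% and 15.4% of it. The log2 fold change of KHSRP was -2.72 with guide 1 (SE 0.06, limma adjusted p = 7.49e-09) and -2.71 with guide 2 (SE 0.06, adjusted p = 7.76e-09). The guides differed by 0.01 in the log2 fold change of KHSRP (95% interval -0.13 to 0.15). In the reference annotation on hg38, KHSRP spans positions 6413348 to 6424794 of chromosome 19, on the minus strand. Where in the gene the guides bind is not given in the sources used here.

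**Figure D1:**
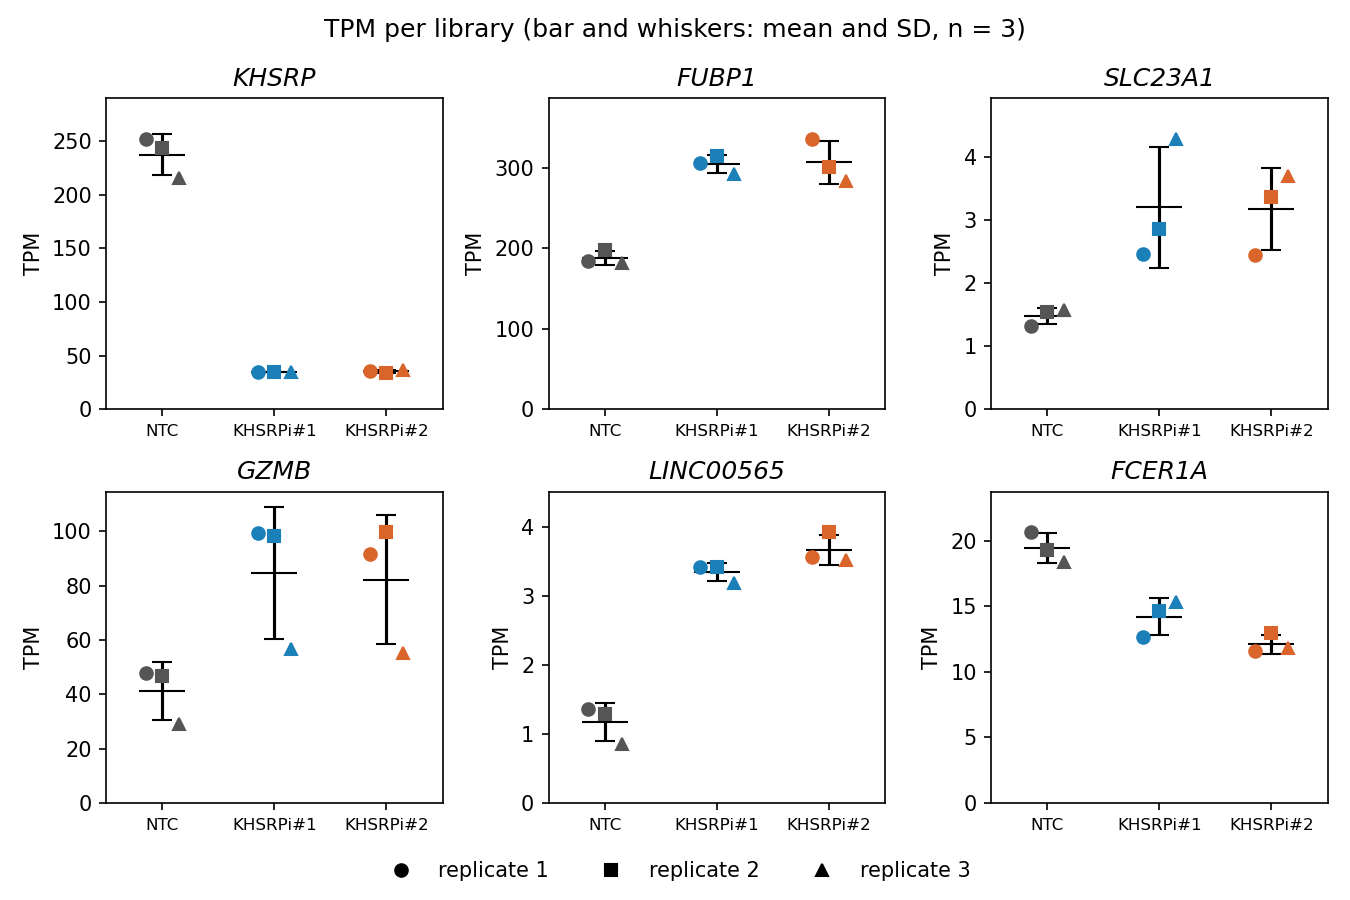
TPM of 6 genes in each library (vertical axes, linear from 0), by group (horizontal axis); symbols mark the replicate number, and bars with whiskers are the mean and SD of 3 libraries. KHSRP lies at about 35 TPM in the knockdown libraries, FUBP1, SLC23A1, GZMB and LINC00565 are higher in all 6 knockdown libraries than in all 3 controls, and FCER1A is lower.

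The comparison of knockdown with control asks which genes are differentially expressed when KHSRP is reduced. Averaged over the guides, FUBP1 rose from 188 ± 8.19 TPM in the controls to 306 ± 18.5 TPM in the 6 knockdown libraries, a log2 fold change of 0.70 (SE 0.06, adjusted p = 0.000905). FUBP1 encodes far upstream element binding protein 1, of the same KH-domain family as KHSRP. The long noncoding RNA LINC00565 rose from 1.17 ± 0.275 to 3.51 ± 0.242 TPM, with a log2 fold change of 1.06 (SE 0.10, adjusted p = 0.00181). The CD1 genes CD1B and CD1E, which encode lipid antigen-presenting molecules, rose as well: CD1B from 6.13 to 8.96 TPM and CD1E from 80.3 to 108 TPM. TCL1B, a relative of the TCL1A oncogene, rose from 129 to 167 TPM. Besides KHSRP, the genes that fell were FCER1A, the alpha chain of the high-affinity IgE receptor (19.4 to 13.2 TPM), PSPC1, a paraspeckle protein (59.3 to 42.7 TPM), and CSTF3, a subunit of the mRNA 3' end cleavage machinery (83.7 to 65.7 TPM).

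These were the 9 genes called on average over the guides at an adjusted p under 0.05 with limma, 5 higher and 4 lower; 867 genes, 7.93% of those tested, had an unadjusted p under 0.05. For all 9 genes the 6 knockdown libraries lay on one side of all 3 controls, which held for 511 of the 10939 tested genes (4.67%, against 2.38% by chance). Rescaling by median ratios or quantile normalization called 4 higher and 5 lower. FUBP1, LINC00565 and KHSRP passed whichever library was left out, while the total ranged from 3 genes without NTC replicate 2 to 7 without KHSRPi#1 replicate 3. CD1B and CD1E did not pass whichever of the 9 libraries was left out, with adjusted p up to 0.317 and 0.114. FCER1A did not pass without 8 of them (up to 0.285), PSPC1 without 7 (up to 0.171), CSTF3 without 7 (up to 0.113), and TCL1B without NTC replicate 2 (0.0879) or NTC replicate 3 (0.066).

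The replicate 3 libraries of all 3 groups stood apart from the others on the first principal component, which held 38.3% of the variance. Between replicate 3 and replicates 1 and 2, 3312 of the 10939 genes differed, 2043 higher and 1269 lower in replicate 3. Each group holds 1 such library, so the comparison was repeated with a term for them, chosen after seeing the data. With this term 192 genes were called on average over the guides, 139 higher and 53 lower, and the 9 genes above were all among them. Median-ratio rescaling in the fit with the term called 138 higher and 109 lower, and quantile normalization 143 higher and 117 lower, so the excess of higher genes is smaller under those scalings. The fit with the term called 34 genes without NTC replicate 3, 78 without NTC replicate 1, and between 90 and 114 without any one library of guide 1 or replicate 3 of guide 2. Fitting replicates 1 and 2 alone, without the term, called 14 genes. Leaving out a single replicate 3 library unbalances the groups. In such a fit without the term, the replicate 3 difference enters the fold changes.

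**Figure D2:**
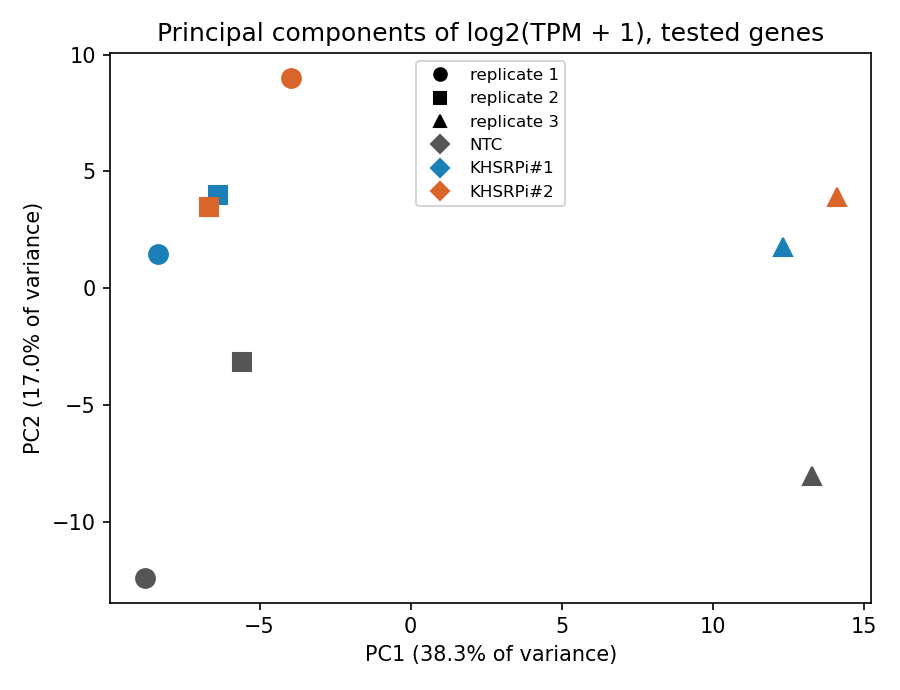
First and second principal components of log2(TPM + 1) over the 10939 tested genes (horizontal and vertical axes, with their shares of the variance); colours mark the group and symbols the replicate number. The 3 replicate 3 libraries lie at 12.3 to 14.1 on the first component, and the other 6 lie below 0.

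SLC23A1 was low in these cells and higher in each knockdown library. It was at 1.48 ± 0.130 TPM in the controls (n = 3), 3.20 ± 0.962 TPM with guide 1 and 3.17 ± 0.650 TPM with guide 2 (n = 3 each). Its log2 fold change averaged over the guides was 0.74 (SE 0.15, 95% interval 0.42 to 1.06). The limma adjusted p of SLC23A1 was 0.167, which does not pass, and 0.00616 with the term for replicate 3. Over its 19 alternatives it ran from 0.00616 to 0.621. An exact permutation test (testing both directions) of the TPM values of this gene alone, 6 libraries against 3, gave p = 0.0238, where the smallest p on one side is 0.0119. With the term for replicate 3, leaving out NTC replicate 3 gave SLC23A1 an adjusted p of 0.0621. SLC23A1 spans positions 139367196 to 139384553 of chromosome 5. SLC23A2, the related vitamin C transporter, was more abundant, at 32.1 TPM in the controls and 34.6 TPM with the knockdown, and its log2 fold change of 0.11 did not pass (adjusted p = 0.691). TET2, an ascorbate-dependent DNA demethylase often mutated in BPDCN, was at 5.62 and 5.98 TPM, and FUBP3 at 60.7 and 61.0 TPM; neither passed. The FUBP3 fold change of 0.01 had the opposite sign under both other scalings. Of 25 tested genes for vitamin C transport and ascorbate-dependent demethylation, SLC23A1 alone passed when adjusted over the list alone; 0 passed over all genes tested with limma, and SLC23A1 with the term. The median (0.01) and mean (0.02) of that list were positive while camera placed it lower than other genes, and it did not pass (adjusted p = 0.541).

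GZMB, the serine protease granzyme B and a gene typical of plasmacytoid dendritic cells, was at 41.2 ± 10.6 TPM in the controls and 83.5 ± 21.6 TPM in the 6 knockdown libraries. Replicate 3 libraries held less of it in every group, and its adjusted p was 0.310 without the term and 8.56e-08 with it. Over its 20 alternatives the adjusted p of GZMB ran from 8.56e-08 to 0.654. In the fit with the term, 23 genes were higher and 8 lower by both guides with all knockdown libraries beyond all controls, against 3 and 1 without it. The 12 with the largest increases were LINC00565, GZMB, SLC23A1, FUBP1, PPP3CB-AS1, TMEM81, CD1B, TCTA, CD1E, TAF9B, BSPRY and MAP1A. The 8 lower genes were KHSRP, FCER1A, PSPC1, CSTF3, CFDP1, OPN3, HNRNPLL and RAD54L, and RAD54L, a DNA repair helicase, had the smallest change at -0.26. Without NTC replicate 3, SLC23A1, PPP3CB-AS1, TMEM81, CD1B, TCTA, CFDP1, HNRNPLL and RAD54L did not pass on average over the guides in the fit with the term (adjusted p from 0.0558 to 0.109); the other 12 of these 20 genes passed there whichever library was left out. Calls by both guides were lost more often: of the 31 genes, 6 were called by both without KHSRPi#1 replicate 3, 8 without NTC replicate 3, 9 without KHSRPi#1 replicate 2, 11 to 17 without any other knockdown library or NTC replicate 1, and 23 without NTC replicate 2. LINC00565, GZMB, FUBP1, KHSRP and CSTF3, and TCL1B beyond the 20 named here, were called by both guides whichever library was left out, CD1E in all fits but that without KHSRPi#1 replicate 3, and the other 14 of the named 20 in 0 to 6 of 9 fits, SLC23A1 in 3. Whether reads were counted by strand is not given in the sources used here, so PPP3CB-AS1 and other antisense genes cannot be told from their partners on the opposite strand.

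The guides were also compared with the controls one at a time and with each other. Guide 1 called 6 genes: LINC00565, FUBP1, SWI5 and TCL1B rose, KHSRP and CSTF3 fell. Guide 2 called 6 genes: the antisense RNA ENO1-AS1, LINC00565, FUBP1 and TCL1B rose, KHSRP and FCER1A fell. Leaving out 1 library, guide 1 called 2 to 4 genes and guide 2 called 3 to 6. With all libraries LINC00565, FUBP1, TCL1B and KHSRP were called by both guides in the same direction. When 1 library was left out, FUBP1 and KHSRP stayed called by both in every fit, LINC00565 in all but those without NTC replicate 2, KHSRPi#1 replicate 1 or KHSRPi#1 replicate 2, and TCL1B in 0 of 9. With the term for replicate 3 the guides called 74 and 88 genes, and 49 were called by both in the same direction, 36 higher and 13 lower. In that fit 6 genes were called by both without KHSRPi#1 replicate 3, 9 without NTC replicate 3, 10 without KHSRPi#1 replicate 2, 16 to 25 without NTC replicate 1 or any other knockdown library, and 51, of which 33 were among the 49, without NTC replicate 2. No gene was called as different between the guides with limma, with or without the term; 115 genes, 1.05% of those tested, had an unadjusted p under 0.05 without it, and 339 with it. Without the filter OPA1-AS1 was called, and in fits of the 2 knockdown groups alone or of replicates 1 and 2 alone, or without NTC replicate 3, RNVU1-11; both were named after their values were seen. ENO1-AS1 had log2 fold changes of 0.35 with guide 1 and 1.26 with guide 2, and the difference of 0.91 (SE 0.16) did not pass (adjusted p = 0.913). SWI5, with 0.43 and 0.19, did not pass as different either (adjusted p = 1.00).

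Across the 10939 tested genes the fold changes of the guides correlated with r = 0.751, and 77.5% had the same sign. Genes are not independent replicates, and both guides were compared with the same 3 controls, which alone raises these values. Simulated unchanged groups sharing those controls gave r = 0.499 and 66.6% on average. The observed covariance was 0.0125 against 0.00822 in the simulations, whose highest was 0.0127. The simulations drew each gene independently, with the spread of the fit without the term. That spread includes the replicate 3 difference, which is balanced between the real groups, so the simulated covariance may be too high. Real deviations are also shared between genes, so the simulated range is not that of unchanged real groups. Independent lists of the sizes called without the term would share 0.00146 higher and 0.000366 lower genes. That expectation leaves out the shared controls, and KHSRP, the target of both guides, is among the genes shared here. Unchanged simulated groups shared 0 in each of 20 runs, but such groups should call few genes at all, so this 0 tests little. The covariance exceeded the simulated mean by 0.00426, or by 0.00358 without KHSRP. With the term, independent lists would share 0.29 higher and 0.0523 lower genes. The 3 controls are too few to split, and part of the excess may come from the shared controls.

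**Figure D3:**
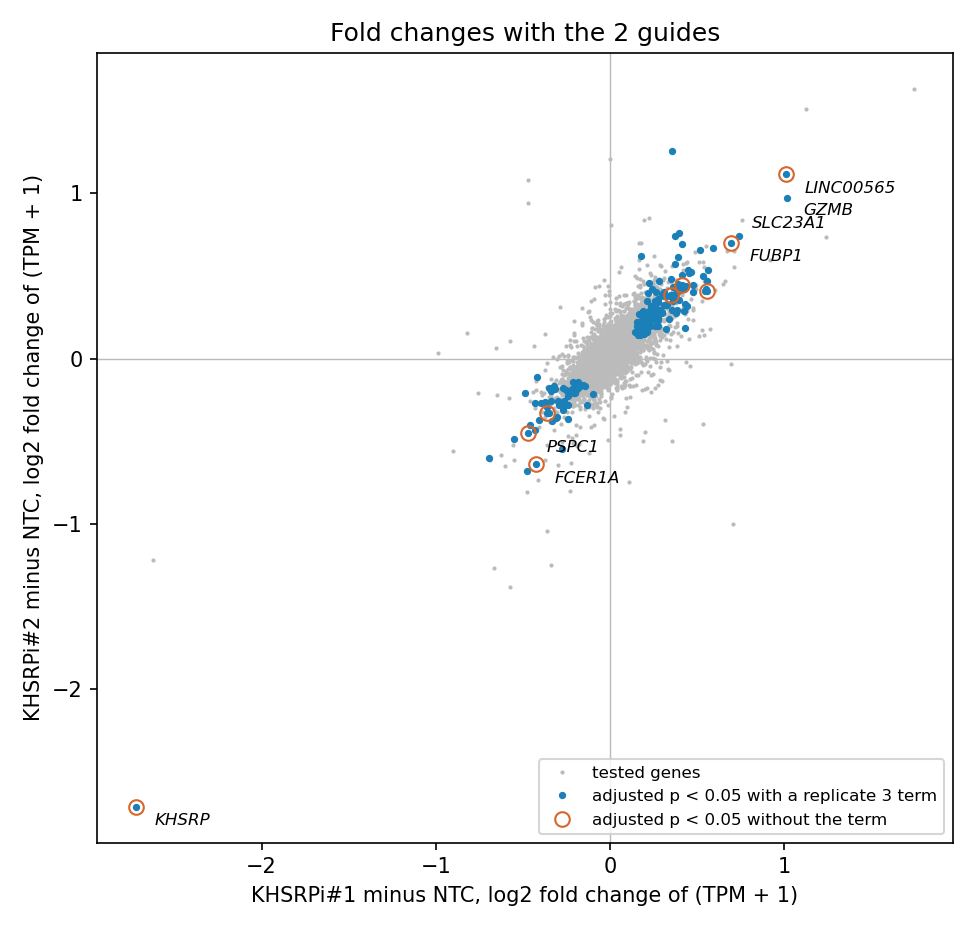
Log2 fold change of TPM + 1 with guide 1 (horizontal axis) and guide 2 (vertical axis), 1 point per tested gene, marked by whether the average over the guides passed with or without the replicate 3 term. KHSRP lies at -2.72 and -2.71, and the fold changes of all tested genes correlate with r = 0.751.

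Gene lists fixed before the data were examined were then compared with all other genes. The median log2 fold change of all tested genes was 0.018 on average over the guides, 0.006 with guide 1 and 0.03 with guide 2. Among the genes that KHSRP is known for, the list of AU-rich element mRNAs (immediate early genes and cytokines) was lower with the knockdown: 17 of its 20 tested members had a negative fold change, with a median log2 fold change of -0.16 (camera adjusted p = 0.000163, and adjusted p = 0.474 with an estimated correlation). Without NTC replicate 3 the median was -0.07 (adjusted p = 0.00431), in a fit with replicate 3 libraries only in the knockdown groups. In the replicate 3 libraries 9 of the 20 were higher and 3 lower than in the others. No member was called over all genes tested or adjusted over the list alone. With the replicate 3 term 4 fell over all genes and 8 adjusted over the list alone; the 4 were JUNB (log2 fold change -0.24), TNF (-0.25), IL1B (-0.36) and PLAUR (-0.16). When each of the 9 libraries was left out in the fit with the term, IL1B passed in all fits but that without NTC replicate 3 (adjusted p = 0.137), JUNB and PLAUR passed in 1 each (up to 0.192 and 0.273) and TNF in 0 (up to 0.164). Without NTC replicate 3 and without the term, the log2 fold changes of TNF, IL1B and PLAUR were -0.14, -0.05 and -0.04. Only the knockdown groups held replicate 3 libraries there, so the replicate 3 difference enters these values. With the term and without NTC replicate 3, IL1B was -0.33 and PLAUR -0.13. TNF ran from -0.29 to -0.19 over the 9 fits with the term. In the list of 24 KH-domain proteins and AU-rich element decay factors FUBP1 rose. ZFP36 and ZFP36L1, whose proteins also promote decay of such mRNAs, fell with the term, by 0.28 and 0.35 on the log2 scale. Without NTC replicate 3, ZFP36 did not pass in that fit (adjusted p = 0.0558), with a log2 fold change of -0.31. ZFP36L1 passed there, and was at -0.21 in the unbalanced fit without the term. Adjusted over the list alone FUBP1 rose and 1 gene fell without the term. That list as a whole did not pass (adjusted p = 0.754), its median of 0.01 being positive and its camera direction lower. The 20 tested let-7 targets did not pass either (adjusted p = 0.139), with 1 gene lower adjusted over the list alone and, over all genes, CCND1 lower with the term, where it passed in 0 of the 9 fits that leave out a library (up to 0.175). With guide 1 the let-7 list was lower (median -0.06, adjusted p = 0.0181, and adjusted p = 0.852 with an estimated correlation), and with guide 2 it did not pass (adjusted p = 0.561), with a median of 0.06 and a lower camera direction. The guide 1 call was lost without NTC replicate 2, NTC replicate 3 or KHSRPi#1 replicate 3 (up to 0.140). KHSRP is also known to take part in let-7 processing. mRNAs with the let-7 motif CTACCTC in the 3' UTR (1100 of 9815) were compared with those without it at equal 3' UTR length. The difference in mean log2 fold change was -0.0035, with an SE over libraries of 0.00461. It did not pass (exact permutation p = 0.452 over libraries, and permutation p = 0.234 over genes).

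All 13 tested members of the MHC class II list had positive fold changes, with a median of 0.11 (camera adjusted p = 9.15e-05, and adjusted p = 0.573 with an estimated correlation). Adjusted over the list alone 2 of them rose, and 0 over all genes tested; HLA-DQA1 and HLA-DRA passed over all genes with the replicate 3 term, with log2 fold changes of 0.26 and 0.18, and 6 adjusted over the list alone. In the fit with the term HLA-DQA1 did not pass without NTC replicate 3 (adjusted p = 0.0851), and HLA-DRA passed in 2 of the 9 fits that leave out a library (up to 0.240). HLA genes are similar enough for reads to be split between them, so single members are uncertain. The list of plasmacytoid dendritic cell and BPDCN identity did not pass (adjusted p = 0.106), but passed with the term (0.00595, from 0.00591 to 0.331 over 20 alternatives, and adjusted p = 0.901 with an estimated correlation), without NTC replicate 1 (0.0367, where its median was 0.05 against 0.08) and with replicates 1 and 2 alone (0.0307). Of its 32 members, 12 were higher and 12 lower in the replicate 3 libraries than in the others. With the term GZMB, CLEC4C, IRF7 and TCL1A rose and LAMP5 fell, 5 of 32 tested members; adjusted over the list alone 2 rose without the term, and 6 rose and 1 fell with it. CLEC4C, the surface marker BDCA-2, had a log2 fold change of 0.36, and IRF7, a regulator of type I interferon, 0.35. Without NTC replicate 3 they were 0.335 and 0.297 with the term and did not pass (adjusted p = 0.0611 and 0.131). In the unbalanced fit without the term they were 0.23 and 0.21. Of the 9 fits with the term that leave out a library, TCL1A passed in 3 (up to 0.0854), LAMP5 in 0 (up to 0.222) and GZMB in all. The NF-kB target list was lower (median -0.07, adjusted p = 0.00576, and adjusted p = 0.573 with an estimated correlation), but did not pass without NTC replicate 1 (adjusted p = 0.0937, median -0.03), and its median was -0.04 without KHSRPi#1 replicate 3 (adjusted p = 0.0381). Of its 19 members 0 were called over all genes or adjusted over the list alone, and with the term 2, TNF and IL1B, which the AU-rich list also holds, and 8 adjusted over the list alone; leaving out 1 library in the fit with the term ended the call of TNF in each of 9 fits, and that of IL1B without NTC replicate 3 (adjusted p = 0.137). Without NTC replicate 3 and the term, in a fit unbalanced for replicate 3, their log2 fold changes were -0.14 and -0.05. With the term IL1B was at -0.33 without that library. Interferon-stimulated genes did not pass (adjusted p = 0.963), and 0 of 25 were called without the term, also adjusted over the list alone. With the term IRF7 rose and IFITM1 and IFITM2, similar genes for antiviral membrane proteins, fell by 0.43 and 0.28 on the log2 scale; adjusted over the list alone 3 rose and 3 fell. IFITM2 did not pass with the term without NTC replicate 3 (adjusted p = 0.0611). Without that library IFITM1 and IFITM2 were at -0.53 and -0.26 with the term. In the unbalanced fit without the term they were at -0.17 and -0.12. Markers of conventional dendritic cells and monocytes did not pass as a list (adjusted p = 0.165); FCER1A was the only one of 13 called over all genes, with or without the term; adjusted over the list alone it alone fell without the term, and 1 rose and 2 fell with it. B cell markers did not pass (adjusted p = 0.752), their median of 0.02 being positive and their camera direction lower. The lists of T and NK cell, erythroid and epithelial markers had under 5 members at a mean TPM of 1.

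Among lists of general cell functions, replication-dependent histones were lower, with 25 of 32 tested members negative and a median of -0.25 (adjusted p = 4.45e-06, and adjusted p = 0.474 with an estimated correlation). The median was -0.14 without NTC replicate 2 (adjusted p = 0.000777) and -0.38 without NTC replicate 1 (4.54e-07). Adjusted over the list alone 4 histone genes fell, and 0 over all genes tested; HIST1H1C, HIST1H2BH and HIST1H2BK fell over all genes with the term, and 6 adjusted over the list alone. Leaving out each of the 9 libraries in that fit, HIST1H1C passed in 8 fits, HIST1H2BH in 7 and HIST1H2BK in 3, with adjusted p up to 0.0759, 0.107 and 0.208; HIST1H1C did not pass without NTC replicate 3, nor HIST1H2BH without NTC replicate 1 or KHSRPi#1 replicate 1. Histone genes are near-identical copies whose reads can be split between them, so single members are uncertain. The most abundant of the list, HIST1H4C, had a mean of 30.1 TPM over all libraries, so the shift concerns genes at modest levels.

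Smaller shifts were a median of -0.02 for 77 cytosolic ribosomal proteins, -0.05 for 25 p53 targets, -0.01 for 34 spliceosome genes, 0.05 for 31 genes of the amino acid and integrated stress response, and 0.06 for 27 genes of the endoplasmic reticulum unfolded protein response. Each of these 5 lists passed with adjusted p between 2.24e-05 and 0.0293, and their adjusted p was between 0.573 and 0.927 with an estimated correlation. Of the 31 stress response genes, 13 were higher and 2 lower in the replicate 3 libraries than in the others. Over all genes 0 members of the 5 lists were called with limma, and adjusted over the list alone 1 spliceosome gene fell. With the term VLDLR and ATF5 of the stress response rose, with log2 fold changes of 0.26 and 0.17, and SRSF4 and U2AF2 of the spliceosome fell, by 0.20 and 0.18 on the log2 scale; adjusted over the list alone 7 stress response genes rose and 1 fell, and 1 spliceosome gene rose and 4 fell. Of the 9 fits with the term that leave out a library, VLDLR passed in 3 (up to 0.136) and ATF5 in 1 (up to 0.280). SRSF4 passed in 4 (up to 0.182) and U2AF2 in 2 (up to 0.161). None of the 4 passed without NTC replicate 3, where ATF5 was 0.14 with the term and 0.07 in the unbalanced fit without it. The most abundant members of the other lists did not pass: BAX (p53) had 187 TPM in the controls and 175 TPM with the knockdown, CANX (endoplasmic reticulum) 1729 and 1825 TPM, and RPS12 (ribosomal) 12350 and 12640 TPM. RPS12 had the opposite sign without NTC replicate 3. Ribosomal proteins did not pass after quantile normalization (adjusted p = 0.125) or without NTC replicate 1 (0.0648), p53 targets at a filter of mean TPM 5 (0.0776), and the stress response without NTC replicate 2 (0.400). The endoplasmic reticulum list did not pass without NTC replicate 3 (0.819) or without replicate 1 or 2 of either guide (up to 0.126). The spliceosome list did not pass after quantile normalization (0.158), with replicates 1 and 2 alone (0.198), or without replicate 3 of guide 1 (0.240) or guide 2 (0.569), and its median was 0.03 without NTC replicate 2 (0.729). Median-ratio rescaling, which put the median of all tested genes at 0 instead of 0.018, also moved these medians. They were then -0.043 for ribosomal proteins, -0.065 for p53 targets and -0.030 for the spliceosome. For the stress response and the endoplasmic reticulum list they were 0.034 and 0.040. Single libraries also moved the medians of these lists by over 1.5 times. The ribosomal median was -0.04 without NTC replicate 2. That of p53 targets was -0.02 without KHSRPi#2 replicate 2 and -0.07 without KHSRPi#1 replicate 3. That of the stress response was 0.02 without NTC replicate 2, 0.03 without KHSRPi#2 replicate 3 and 0.11 without NTC replicate 3. That of the endoplasmic reticulum list was 0.02 without NTC replicate 3, 0.03 without KHSRPi#2 replicate 1, 0.09 without NTC replicate 2 or KHSRPi#1 replicate 3, and 0.10 without KHSRPi#2 replicate 3. The spliceosome median was -0.04 without NTC replicate 3, -0.03 without KHSRPi#2 replicate 1, -0.02 without replicate 2 of either guide, 0.00 without KHSRPi#1 replicate 3 and 0.01 without KHSRPi#2 replicate 3. In replicate 3 libraries the endoplasmic reticulum and spliceosome lists were lower than in the others, by medians of -0.16 and -0.06 (adjusted p = 3.14e-06 and 7.31e-06, and adjusted p = 0.784 for both with an estimated correlation). Genes of the cell cycle, glycolysis, respiration and apoptosis did not pass as lists on average over the guides.

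Some lists passed with 1 guide and not the other, and the difference between the guides was tested with camera, a test chosen after the data were seen. Cytosolic ribosomal proteins were lower with guide 2 (median -0.04, adjusted p = 9.71e-13, and adjusted p = 0.609 with an estimated correlation) and did not pass with guide 1 (median -0.01, adjusted p = 0.407). With guide 2 respiratory chain complexes III, IV and V (adjusted p = 0.0199) and mitochondrial ribosomal proteins (0.0235) were lower, by medians of -0.03 and -0.01, with adjusted p = 0.772 for both with an estimated correlation; with guide 1 they did not pass (0.426 and 0.348). Both guide 2 calls were lost without NTC replicate 1 or KHSRPi#2 replicate 1, that of the complexes also without NTC replicate 3, and that of the mitochondrial list also without KHSRPi#2 replicate 3 (up to 0.769 and 0.676). These 3 lists were lower with guide 2 than with guide 1 (adjusted p = 7.38e-22, 1.57e-09 and 7.07e-10), as were histones (4.76e-07), with adjusted p = 0.240 for each of the 4 with an estimated correlation. The spliceosome list passed with guide 2 (0.0199, and adjusted p = 0.911 with an estimated correlation) and not with guide 1 (0.0812), and the endoplasmic reticulum list with guide 1 (0.0182, and adjusted p = 0.896 with an estimated correlation) and not with guide 2 (0.069, and 0.013 with the term). The guide 2 call of the spliceosome was lost without NTC replicate 2 or KHSRPi#2 replicate 3 (up to 0.812), and the guide 1 call of the endoplasmic reticulum list without NTC replicate 3, KHSRPi#1 replicate 1 or KHSRPi#1 replicate 2 (up to 0.678). Neither of these 2 lists passed as different between the guides (0.538 and 0.890). In all 8 of 40 lists differed. Of the other 4, camera placed let-7 targets higher with guide 2 relative to other genes (0.0366). It placed lower MHC class II (0.0425, and 0.0571 with the term), respiratory chain complex I (7.41e-05) and antioxidant genes (0.0196). With an estimated correlation these 4 had adjusted p = 0.965, 0.965, 0.240 and 0.485, and 0 of 40 lists differed. Fry called 0, with a lowest adjusted p of 0.916. The MHC class II median was 0.110 with guide 1 and 0.119 with guide 2, with a median difference of its members of -0.027. For antioxidant genes the median was 0.022 with each guide, with a median difference of -0.003. The call of complex I was lost without KHSRPi#2 replicate 1 (0.158), that of antioxidant genes without KHSRPi#1 replicate 1 or 2 or KHSRPi#2 replicate 3 (up to 0.396), that of let-7 targets without any library of guide 1 or replicate 1 or 3 of guide 2 (up to 0.328), and that of MHC class II without NTC replicate 3, replicate 2 or 3 of guide 1 or replicate 1 or 2 of guide 2 (up to 0.559). With the term 10 lists differed: all of these 8 but MHC class II, and also AU-rich element mRNAs (0.0405), which were less low with guide 2, and, lower with guide 2, MHC class I (0.0265) and MYC-associated nucleolar genes (0.00664). With an estimated correlation 0 differed there either, with adjusted p = 0.516, 0.727 and 0.727 for these 3 and a lowest of 0.069 for mitochondrial ribosomal proteins; fry called 0. In the fit with the term the AU-rich call was lost without NTC replicate 1, replicate 2 or 3 of guide 1 or replicate 3 of guide 2 (up to 0.673), that of MHC class I without replicate 2 or 3 of either guide (up to 0.111), and that of MYC-associated genes without KHSRPi#2 replicate 2 (0.0841).

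The 13 tested genes near KHSRP on chromosome 19 were slightly lower than other genes, with a median of -0.07 and 10 of 13 negative (adjusted p = 0.00576, and adjusted p = 0.574 with an estimated correlation). None was called on average over the guides, with or without the term; adjusted over the list alone 0 fell, and 2 with the term. CLPP, the most abundant, went from 123 to 114 TPM. Without NTC replicate 3 the list did not pass (adjusted p = 0.107), nor without the filter on low values (0.057). The median was -0.16 without NTC replicate 2, -0.11 without KHSRPi#1 replicate 3, -0.10 without KHSRPi#2 replicate 3 and -0.04 without KHSRPi#1 replicate 1. After removal of a trend with GC content and transcript length this list did not pass (adjusted p = 0.207); its mean distance from other genes went from -0.09 to -0.05, its median from -0.07 to -0.06, and the negative members from 10 to 9.

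In all, 10 of 40 tested lists passed, 3 higher and 7 lower, and 11 passed with the replicate 3 term. With an estimated correlation 0 of 40 passed in either fit, the lowest adjusted p being 0.474 without the term and 0.185 with it. Of the 84 ways to divide the 9 libraries into 6 and 3, 31 called at least as many lists as the real one, so the number of lists called does not exceed what regrouping the libraries gives.

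**Figure D4:**
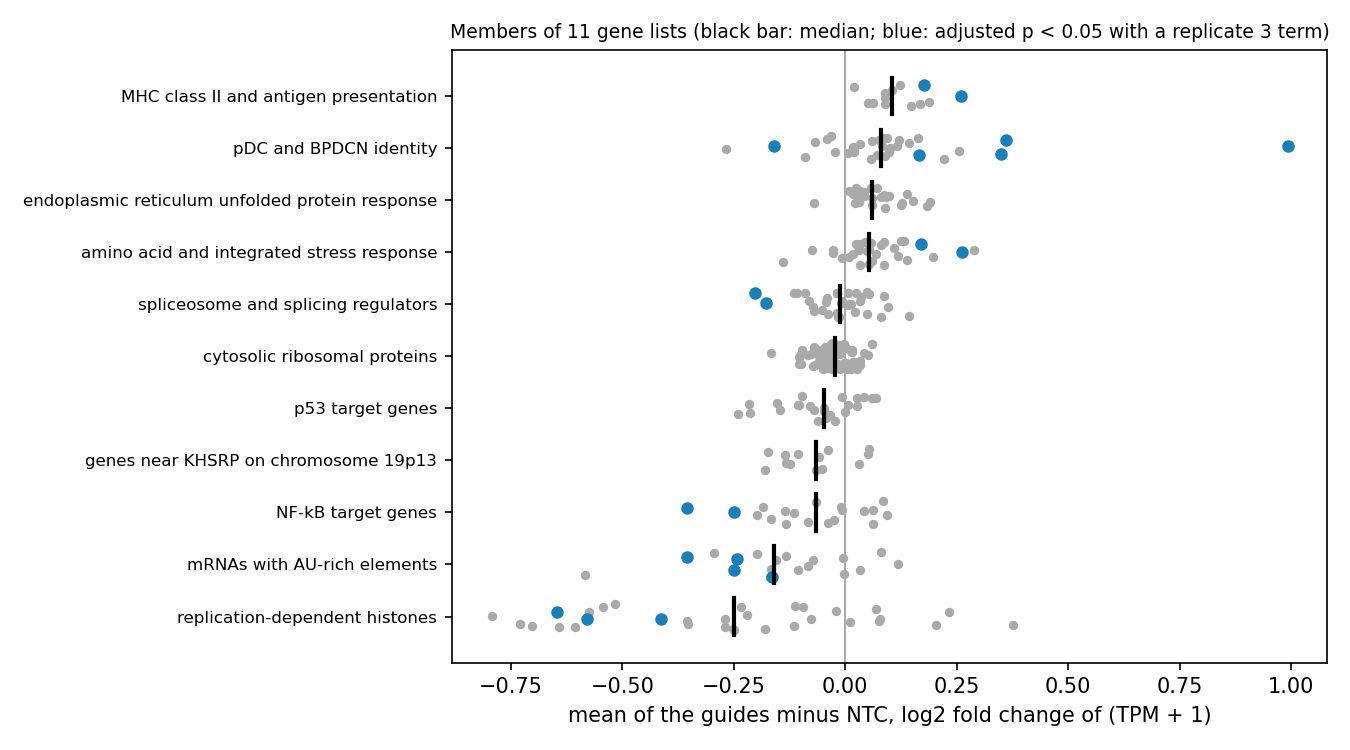
Log2 fold change of TPM + 1, mean of the guides minus control (horizontal axis), of each tested member of the 11 lists that passed in either fit (rows); black bars are medians and blue points are members called with the replicate 3 term. Medians run from -0.25 for histones to 0.11 for MHC class II.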

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

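The replicate 3 term, leaving out libraries in the fit with it, the fit of replicates 1 and 2 alone and the test of lists between the guides were chosen after the data were seen. TPM gives no read totals, so what depth limits is known only through the spread of replicates. KHSRP kept its direction and passed under all 21 alternatives for each guide, and FUBP1 under all 20. SLC23A1 kept its direction under all 19 alternatives; it has no value at a filter of mean TPM 5, where it is left out, and leaving out single libraries gave 0.65 to 0.81. It passed with the replicate block (log2 fold change 0.74, adjusted p = 0.00643) and the replicate 3 term (0.74, adjusted p = 0.00616), whose smaller residual spread is the difference.

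The replicate 3 term called 74 genes for guide 1, 88 for guide 2, 192 for the mean of the guides and 49 for both guides. Replicates 1 and 2 alone called 14 for the mean and 1 between the guides. Fits of only the groups compared called 2 for guide 1, 3 for guide 2 and 1 between the guides. A minimum log2 fold change of 1 left 2, 3 and 2 for guide 1, guide 2 and the mean, and 2 for both guides. No filter gave 1 between the guides. The genes called between the guides, named after their values were seen, were OPA1-AS1 without the filter and RNVU1-11 in both smaller fits and without NTC replicate 3. Camera with an estimated correlation called 0 lists and fry 0, against 10. With the replicate 3 term fry called 1 list for the mean of the guides, 2 for guide 1 and 0 for guide 2, and camera with an estimated correlation called 0 in each. Apart from the fits named, the cause was not tested.

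Leaving out 1 library gave 2 to 4 genes for guide 1, 3 to 6 for guide 2, 3 to 7 for the mean, 2 to 4 for both guides and 0 to 1 between them, where fewer libraries enter each fit. Leaving out a replicate 3 library also unbalances the groups, and these fits had no term for it. The correlation of the guides ran from 0.644 without KHSRPi#1 replicate 3 to 0.810 without NTC replicate 3, and lists from 8 to 12. With the replicate 3 term, the mean of the guides called 34 genes without NTC replicate 3, 78 without NTC replicate 1 and 202 without NTC replicate 2, and 30, 73 and 130 of these were among the 192; leaving out a knockdown library left 90 to 132. Both guides then called 6 genes without KHSRPi#1 replicate 3, 9 without NTC replicate 3, 10 without KHSRPi#1 replicate 2, 51 without NTC replicate 2 and 16 to 25 without each of the others.

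Same-numbered libraries correlated in their deviations from the group means by 0.04 to 0.63, with 1 pair under 0.1, and 4 of 9 correlated best with their own number, so the numbers were not taken to pair the samples. The replicate block called 54 genes for guide 1, 91 for guide 2, 152 for the mean, 37 for both guides and 1, GBAT2, between them. With it the spliceosome list did not pass, the list of plasmacytoid dendritic cell identity passed, and ZFP36 and ZFP36L1 were called.

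FUBP3, near 0, turned to -0.013 with median-ratio rescaling, -0.003 with quantile normalization, and -0.009 without KHSRPi#1 replicate 2, with a range from -0.025 without KHSRPi#2 replicate 1 to 0.022 without KHSRPi#2 replicate 2. RPS12 turned to -0.014 without NTC replicate 3, and was 0.070 without NTC replicate 1. Among other named genes and lists 89 values newly passed and 69 no longer passed.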

Other observations

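The comparison of gene lists between replicate 3 and the other libraries, the comparison of library depths and the fits with a replicate 3 term were chosen only after the result was seen.

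The replicate 3 libraries differed from replicates 1 and 2 in genes of sterol and lipid synthesis and of ribosome biogenesis, among others. Over all 10939 tested genes 2043 were higher and 1269 lower in replicate 3, against which the counts below are to be read. Of 24 tested genes for cholesterol synthesis and uptake, 21 were higher in replicate 3 and 0 lower, with a median log2 difference of 0.33 (camera adjusted p = 2.32e-09, and adjusted p = 0.784 with an estimated correlation). Of 14 genes for fatty acid synthesis and desaturation, 9 were higher and 0 lower, with a median of 0.24 (adjusted p = 0.000253, and adjusted p = 0.784 with an estimated correlation). Of 41 nucleolar and ribosome biogenesis genes associated with MYC, 34 were lower and 1 higher, with a median of -0.19 (adjusted p = 3.63e-18, and adjusted p = 0.251 with an estimated correlation). Hypoxia-inducible factor targets were higher (median 0.17, adjusted p = 0.00311, and adjusted p = 0.784 with an estimated correlation). Cytosolic heat shock proteins were lower, 9 of 17 (median -0.14, adjusted p = 0.000343, and adjusted p = 0.784 with an estimated correlation). Mitochondrial ribosomal proteins were lower, with 21 of 69 lower and 3 higher (median -0.05, adjusted p = 0.000253, and adjusted p = 0.300 with an estimated correlation). Long noncoding and small host RNA genes were lower, 8 of 20 (median -0.05, adjusted p = 0.0092, and adjusted p = 0.784 with an estimated correlation). The endoplasmic reticulum and spliceosome lists were lower as well (medians -0.16 and -0.06, adjusted p = 3.14e-06 and 7.31e-06, and adjusted p = 0.784 for both with an estimated correlation).

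That replicate 3 stands apart is not accounted for by depth, since 4 of the other libraries have a relative depth inside the range of the replicate 3 libraries. A trend with GC content and transcript length does not account for it either, since 4643 genes differed after its removal and the difference correlated with GC content at r = 0.01 across genes. A difference in culture, harvest or library preparation may lie behind it and was not tested, because the labels give 1 batch. Each group holds 1 replicate 3 library, so the difference adds spread within each group.

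The lower values of genes near KHSRP may come in part from GC content. These genes are GC-rich, with a median of 60% against 48.1% for all tested genes, and knockdown fold changes fell with GC content across genes (r = -0.29). The steepest slope was in NTC replicate 1, at 0.09 log2 units per 10% of GC content. Slopes of the other libraries ran from -0.04 to 0.01, so this trend rests largely on that library. Without that library the list's median was -0.064 against -0.065 with all libraries, and the list still passed (camera adjusted p = 0.0466). The lower values thus did not rest on that library. Removing the trend moved the list's mean distance from other genes from -0.09 to -0.05 (SE over members 0.02 before and after) and ended the call (adjusted p = 0.207), while the median went from -0.07 to -0.06 and the negative members from 10 to 9 of 13; the call ended with the smaller mean distance. Spread of the interference along the chromosome stays open: the 5 tested genes within 100 kb had a median 0.03 below that of the 22 genes up to 1 Mb away (difference -0.029, one-sided permutation p = 0.183).

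The AU-rich element list was lower although KHSRP is known to promote decay of such mRNAs. A trend with GC content and length does not account for it, since the list still passed after removal (camera adjusted p = 0.00335 at the preset correlation). Its mean distance from other genes was then -0.15 against -0.17 before. With an estimated correlation the list had not passed before removal (adjusted p = 0.474). No general fall of mRNAs with AU-rich motifs was seen, but the comparison cannot exclude a small one. mRNAs with TATTTAT in the 3' UTR (3474 of 9815) were compared with those without it at equal 3' UTR length. Those with it were higher by 0.0086 in mean log2 fold change, with an SE over libraries of 0.0116 (exact permutation p = 0.5 over libraries, and p = 3e-04 over genes). GC content was not matched, and fold changes fell with GC content (r = -0.29), which may place mRNAs with such motifs higher. That trend rests largely on NTC replicate 1, the library with the steepest slope. For the shorter motif ATTTA (7243 of 9815) the difference was 0.0436 higher, with GC content not matched (SE over libraries 0.0264, exact permutation p = 0.107 over libraries, and p = 1e-04 over genes, the smallest these permutations give), and 13 of the 20 list members have TATTTAT. The difference of 0.0086 for TATTTAT (SE over libraries 0.0116) argues against a general fall of such mRNAs as large as the list's mean distance of -0.17. A smaller general fall stays open. So does a change in transcription of these inducible genes, which may be a response to the knockdown and was not tested. Chance in how the libraries fall into groups also stays open, as for all lists here.

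Other divisions of the libraries were counted for each number of called genes. Comparing 6 libraries with 3 in a fit of 2 groups called 13 genes for the real groups, and 2 of 84 divisions, the real one included, called as many. The other was replicate 3 against the rest, with 2885 genes, which points to a structure of the samples. With the replicate 3 term, 218 genes were called for the real groups, and of the 45 divisions that keep 1 replicate 3 library in the group of 3 only 1, the real one, called as many; the highest of the others was 2. Regrouping these libraries therefore seldom gave as many genes as the real groups. The targeted gene KHSRP counts towards the real groups, and the term was chosen after seeing the data. A difference in culture or preparation that follows the groups would give the same result and is not excluded. For genes called by both guides, 2 of 100 drawn groupings, the real one included, called as many as the 4 observed. The highest of the others was 4, equal to the real groups. These draws did not keep 1 replicate 3 library in each group, and KHSRP, the target, is among the 4. Few draws thus reached the observed count, but chance is not excluded by them. For single guides there are 10 divisions, too few for a share under 0.05: fits of 2 groups called 2 genes for guide 1 and 3 for guide 2, and 1 between the guides, and the highest of the others was 1 in each case. The real groups were among the 1, 1 and 2 divisions with as many.

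For the gene lists chance cannot be excluded. Of the 84 divisions, 31 called at least the 10 lists of the real groups, and the highest of the others was 16. With the replicate 3 term 10 of 45 called at least 11, and the highest of the others was 15.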
